A study of Mus musculus with 2 samples.

How the data were processed

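H3K36me3 was measured by ChIP-seq in newborn mouse kidney in 2 biological replicates of 1 group. Per the labels, sonicated fragments had a size range of 300 to 500 and both sexes were pooled in each replicate; that the unit is bp was taken from usual practice. Both replicates carry the same donor identifier in the labels, which also describe them as separate biological replicates from pooled mice, and they were treated as 2 samples. The values used were 4 peak lists in the narrowPeak layout: 1 list for each replicate, 1 made from the alignments of both replicates together (the pooled list), and 1 derived from the other 3 (the replicated list), per the deposited text that accompanies them. The lists were made on the mouse assembly mm10, per the labels. The aligner, the peak caller, its version and its threshold, the control reads and the read depth are not given in the sources used here, nor is the overlap rule behind the replicated list.

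The deposited signal value of each peak is the authors' own measure of enrichment; what it is relative to is not given in the sources used here, so it was used only to rank and filter peaks within a list. The deposited −log10 p of each peak was used in the same way, and the lowest values in the 4 lists lay between 2.01 and 2.03. The deposited −log10 q was not used to filter peaks, and its lowest values were 0.436 in replicate 1, 0.506 in replicate 2 and 0.606 in the pooled and replicated lists. The deposited display score was not used. Because peaks are called regions, a gene without a peak is one in which no enrichment passed the authors' caller, and the amount of the mark below that limit was not measured. The limit falls with depth, which can differ between the replicates and is deeper in the pooled alignments.

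Genes, exons and strands came from GENCODE release M21 (GRCm38, the same assembly as mm10; chromosome lengths were compared and every peak ended within its chromosome). Genome sequence with repeats in lower case came from the RefSeq copy of the same assembly. Positions are 1-based. One protein-coding gene per symbol with a span of at least 1 kb on chromosomes 1 to 19, X and Y was kept, 21196 in all. Coverage is the percentage of the span from the first to the last annotated base that lies under peaks, with overlapping peaks merged, and a gene covered over at least 25% by the replicated list was called marked. The replicated list gave the main value, and each replicate's own list gave a second value, from which the mean and SD over the 2 replicates were taken.

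Peaks of the replicates were counted as shared where at least 50% of a peak's own length lay under the other list, and the shares were set against 1000 random circular shifts of one list within chromosomes. The genome was divided into exons, introns, 1 kb upstream of gene starts, 5 kb downstream of gene ends and other sequence, each base in the first class that fits, and the share of covered bp in each class was divided by its share of the genome outside assembly gaps. Position was measured in 10 equal parts of the span of marked genes of at least 10 kb. Flanks were measured for those with no other gene within 10 kb on that side. Shares of genes on chromosomes have exact (Clopper-Pearson) 95% intervals, which cover counting error only.

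Fixed lists of genes were compared with 10000 random lists of the same size drawn from the same 20 bins of gene length. A list was called where its median coverage stood at or above the 97.5th or at or below the 2.5th percentile; ties counted at mid-rank. The 31 lists were markers of 8 kidney cell types, 6 lists labelled as other tissues, 6 programmes and 11 families taken by symbol. The lists labelled as other tissues include immune and erythroid cells. The programmes were housekeeping, cell cycle, oxidative phosphorylation, H3K36 methylation, imprinting, and cystic kidney and ciliary disease. The genes named were fixed by rule: a set of 14 named in every case (Six2, Wt1, Pax2, Ret, Nphs1, Slc34a1, Umod, Foxd1, Pecam1, Setd2, Alb, Snap25, Ckm and Hba-a1), the 2 highest and the lowest of each kidney list, the highest and the lowest of each list of another tissue, the 10 highest genes of at least 20 kb, the 3 genes of at least 20 kb with the largest difference between replicates in each direction, and the 5 longest regions outside genes, of which there were none. Ties went to the longer gene, and other members of a list serve as examples of it. The groups, tests, lists and rule were fixed before the data were examined. Named genes outside the rule, such as the marked genes on the X, Safb and the genes under the strongest peaks, were chosen after their values were seen.

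Alternatives were the pooled list, each replicate's own list, a deposited −log10 p of at least 5, the upper 50% of peaks by signal value, 10% and 50% as the level that calls a gene marked, a minimum length of 5 kb, spans without overlapping genes, peaks merged across gaps of up to 1 kb, no matching on length, other overlap rules, other gaps and gene types for regions outside genes, and the removal of the 1% of peaks with the highest signal value. The mean in place of the median, the removal of genes within 5 kb of a marked gene, and matching on length, GC content and repeats were added after the data had been seen. No test between groups was possible with 1 group, and no depth correction was made.

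Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The list percentile was tested on simulated data: 100 lists of 20 genes were drawn from the 21196 genes and raised by a known amount. A rise of 20 points was called in 100 of 100 lists, 10 points in 62, 5 points in 20 and no rise in 0. Only the upper threshold and the median were simulated, with coverage shuffled among genes of similar length. The lower threshold, the mean and likeness between neighbouring genes were not covered. The interval arithmetic was checked on 4000 random regions with 0 errors.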

Results

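Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark laid down in the bodies of transcribed genes by the methyltransferase SETD2, was mapped by chromatin immunoprecipitation and sequencing in kidney tissue of newborn mice (postnatal day 0). Both sexes were pooled. The series held 1 group with 2 biological replicates; replicate 1 came from the kidneys of 15 mice, and the number of mice behind replicate 2 was not given in the sources used here. No second condition, tissue or age was part of the series, so the questions addressed were where the mark lay in the genome, which genes carried it, and how well the replicates matched. The values deposited for each replicate were peak positions with the peak caller's statistics. Read depth was not given in the sources used here, and spread is therefore given only as that between the 2 replicates. Throughout, the coverage of a gene is the percentage of its annotated span that lay under peaks. The value from the replicated peak list stands first, and the mean over the 2 replicates' own lists with its SD (n = 2) follows. That SD describes the replicates' own lists and does not measure the precision of the replicated value. Coverage by the replicated list was often above that of both replicates because its peaks were called on the pooled alignments. A gene with at least 25% of its span covered by the replicated list is called marked, and no coverage means none by that list unless another is named. Percentiles and p-values in what follows describe these libraries, since genes are not replicates.

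Replicate 1 had 135966 peaks over 47.3 Mb and replicate 2 had 171799 peaks over 61.7 Mb, which were 1.79% and 2.33% of the genome. The pooled list held 210316 peaks over 91.7 Mb, and the replicated list 94035 peaks over 62.7 Mb. The median peak length was 273 bp in each replicate and 515 bp in the replicated list. The longest peak in the replicated list spanned 12972 bp on chromosome 15 (76171790 to 76184761) within Plec, the gene of the cytoskeletal linker plectin, and exons made up 83.0% of it. Replicate 2 covered 1.30 times as many bp as replicate 1.

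Of the peaks of replicate 1, 71232 (52.4%) had at least 50% of their length covered by replicate 2, and 63808 peaks of replicate 2 (37.1%) were covered in the same way by replicate 1. When one list was moved around each chromosome by random distances, the mean shares were 2.56% and 1.93%, and 0 of 1000 such shifts reached the observed values. The covered bp had a Jaccard index of 31.0% against a shifted mean of 1.14%. Peaks of both lists lay mostly in genes, and shifts move them off genes. The shifts therefore do not test agreement beyond a shared location in genes. Among the strongest 10% of peaks by the authors' p, 79.2% of those in replicate 1 and 65.9% of those in replicate 2 were shared, and among the weakest 10% the shares were 36.2% and 22.3%. The coverage of whole genes had a Pearson correlation of 0.954 and a Spearman correlation of 0.936 between the libraries across 21196 protein-coding genes, which are not independent replicates and of which 43.3% had no coverage in any list. By their own lists, 2157 genes were marked in replicate 1 and 3140 in replicate 2. The 2029 genes marked in both made up 94.1% of those of replicate 1 and 64.6% of those of replicate 2, which alone marked 1111 more. Of the 3268 genes marked in either, 2842 had the higher coverage in replicate 2, by a mean of 7.54 points over all 3268.

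Single genes differed between the replicates in both directions. Among genes of at least 20 kb, the largest differences towards replicate 2 were in Adsl, which encodes the purine synthesis enzyme adenylosuccinate lyase (29.8% in replicate 1 and 54.3% in replicate 2), in Ufd1, a partner of the p97 segregase (38.4% and 62.6%), and in Plekha3 (19.5% and 42.7%). The largest towards replicate 1 were smaller and concerned Mkrn2 (34.6% and 24.9%), Urm1, which encodes a ubiquitin-like protein (23.1% and 14.1%), and Bpnt1 (32.4% and 24.2%). These genes were selected for their differences.

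Every peak of the replicated list was present with the same coordinates in the pooled list, of which it kept 44.7%. Of the replicated peaks, 51.4% had at least 50% of their length covered in both replicates and 78.3% had at least 1 bp covered in both. Of the 48367 pooled peaks with at least 50% covered in both, 48363 had been kept. Pooled peaks among the strongest 10% by p were kept in 99.2% of cases and those among the weakest 10% in 4.95%.

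The mark lay almost wholly inside genes. Annotated genes held 96.9% of the bp covered by the replicated list (96.6% ± 0.171, SD, n = 2) and 46.1% of the genome. Exons were covered 5.89 times as often as their share of the genome (5.67 ± 0.159) and introns 1.66 times (1.67 ± 0.0145). The 1 kb upstream of genes was depleted to 0.0792 of its genomic share (0.0880 ± 0.00151), the 5 kb downstream of genes to 0.508 (0.535 ± 0.0342), and all other sequence to 0.00164 (0.00560 ± 0.000512). All these departures from 1 were larger than the spread between replicates.

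Along gene bodies, coverage rose from the start towards the 3' end. In the 2611 marked genes of at least 10 kb, the first of 10 equal parts of the span was covered at 3.11% (2.86% ± 0.665), the fifth at 48.0% (37.7% ± 5.87) and the ninth at 60.6% (46.7% ± 6.51). In the last part coverage was 53.3%. The 3' side of the gene midpoint was covered 2.03 times as much as the 5' side (1.98 ± 0.0756), and 2354 of the 2611 genes (90.2%) had the higher coverage on the 3' side. First exons were nearly bare. In the 2516 such genes outside the Zfp family with at least 3 exons, first exons were covered at 0.646% (0.634% ± 0.0676), internal exons at 61.4% (48.7% ± 6.55) and last exons at 52.8% (41.1% ± 5.30). Past the gene end, in the 648 genes with no other gene within 10 kb on that side, coverage was 30.3% in the first kb (24.2% ± 5.36), 11.9% in the second kb and 1.02% in the fifth kb. The first kb upstream of 812 such genes held no replicated peak (0.0151% ± 0.0214 in the replicates). Marked genes were chosen by their coverage, so the levels within them are high by construction, and the shape along the gene is the measurement.

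**Figure D1:**
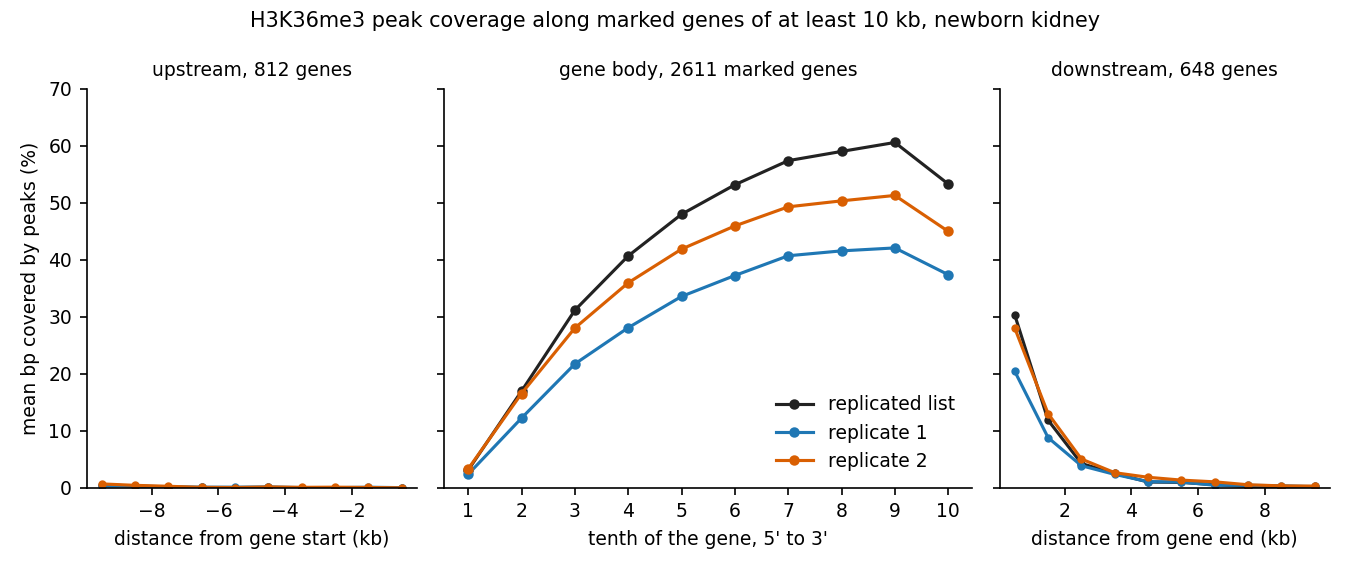
Mean percentage of bp covered by H3K36me3 peaks (vertical axis) in the 10 kb upstream of marked genes, in 10 equal parts of the gene body from 5' to 3' (2611 genes of at least 10 kb), and in the 10 kb downstream, for the replicated list (black), replicate 1 (blue) and replicate 2 (orange). Replicated coverage rose from 3.11% in the first part to 60.6% in the ninth, and fell from 30.3% in the first kb past the gene end to 1.02% in the fifth.

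Of 21196 protein-coding genes of at least 1 kb, 3523 (16.6%) were marked and 11576 (54.6%) had no coverage by the replicated list. The pooled list left 9621 genes without coverage, and 9185 (43.3%) had none in any of the 4 lists. At least 10% in both replicates was reached by 3488 of the marked genes, and at least 25% in both by 2028 (57.6%). The number of marked genes depended on the level chosen: 6221 genes were covered over at least 10% and 934 over at least 50% of the span. It was 2171 when only the upper 50% of peaks by signal value were used and 4983 with the pooled list. By length, 8.34% of genes of 1 to 5 kb were marked, 25.4% of genes of 10 to 20 kb, 3.69% of genes of 100 to 300 kb and 0 of the 566 genes of 300 kb or more. For 168 marked genes, the part of the span that no other protein-coding gene overlapped was covered below 25%.

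Among genes of at least 20 kb, Safb2, a nuclear scaffold attachment and RNA-binding protein (chromosome 17, 56560965 to 56584585, minus strand), had the highest coverage, with 85.8% of its 23621 bp under peaks (65.1% ± 10.3). Sf3b3, a subunit of the U2 small nuclear ribonucleoprotein, followed with 82.0% (67.4% ± 7.90), then Trrap, the scaffold of histone acetyltransferase complexes (chromosome 5, 144767732 to 144859778), with 81.6% (65.8% ± 6.91), and Kmt2d, a histone H3 lysine 4 methyltransferase, with 80.9% (68.1% ± 2.40). The other genes among the 10 highest were Exosc10, a catalytic subunit of the RNA exosome, with 80.1%, the polarity gene Scrib with 79.8%, Hnrnpul1 with 79.6%, 2610507B11Rik with 78.2%, the splicing regulator Rbm5 with 77.95% and Gtf3c1, a subunit of an RNA polymerase III initiation factor, with 77.9%. In each of these 10 genes both replicates gave at least 54.9%, and the SD between replicates ran from 0.116 points (Scrib) to 14.4 points (Rbm5).

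Safb2 lies head to head with Safb, which had 75.3% of its span covered (62.4% ± 1.80), and their annotated starts are 239 bp apart. No replicated peak lay in the 3849 bp from 56582789 to 56586637 on chromosome 17, which hold both starts and the first exons of both genes. Replicate 2's own list had 1 peak there (56583265 to 56583459, −log10 p 3.14), and a replicate 1 peak ended just inside it, at 56582795. On either side, 9 replicated peaks lay in Safb2 and 13 in Safb.

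**Figure D2:**
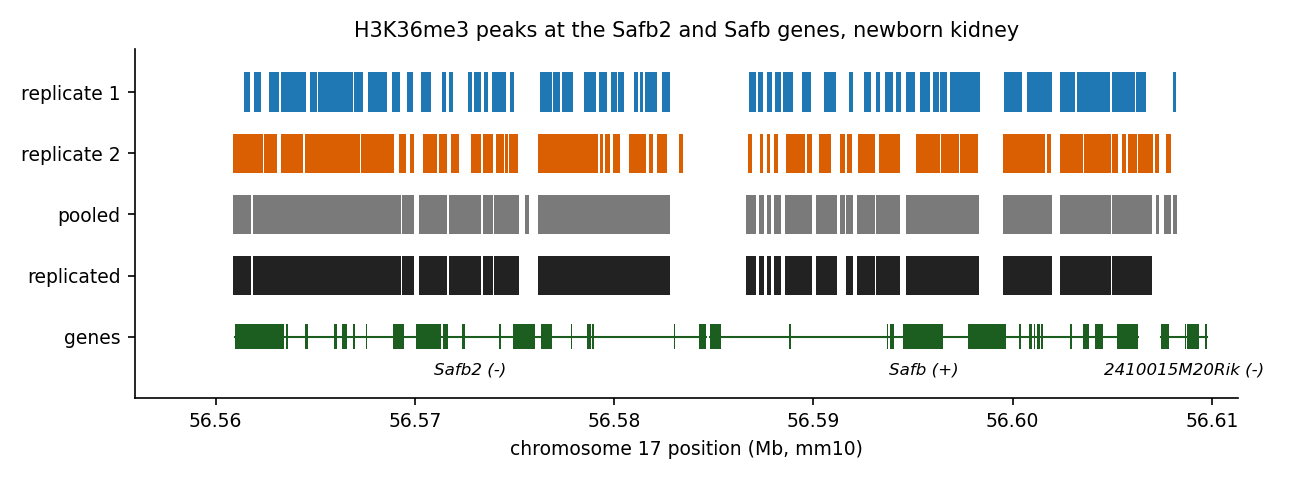
Map of chromosome 17 (mm10 position in Mb, horizontal axis) with H3K36me3 peaks of replicate 1, replicate 2, the pooled list and the replicated list as filled bars, and GENCODE genes with exons as boxes and introns as lines, strand in parentheses. Peaks covered 85.8% of Safb2 and 75.3% of Safb in the replicated list, and the 3849 bp around the paired gene starts held no replicated peak.

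Genes of general cell programmes were marked far more often than genes of the same length at random. Of the 31 lists and families compared with 10000 random lists matched on gene length, 7 had a median coverage within the top 2.5% of random lists. None lay within the bottom 2.5%, but 21 of the 31 had a median of 0, which ties with random lists and put that tail largely out of reach. Of 17 oxidative phosphorylation genes, 14 were marked (13 and 14 in the replicates' own lists), with a median of 43.6% (medians of the replicates 36.9% ± 7.43) at the 100th percentile. They included Atp5b and Atp5a1, which encode the beta and alpha subunits of ATP synthase, with 64.3% and 61.1%, and Ndufa10 of complex I with 63.2%, while Cox7c had no coverage. Of 20 cell cycle genes, 12 were marked (9 and 11), with a median of 33.9% at the 100th percentile. The replicative helicase subunits Mcm3 (69.3%, 47.7% ± 0.497) and Mcm2 (66.7%) led, Cdk1 had 44.3% and Mki67 44.0%, and Ccnb1 and Ube2c had no coverage. Of 20 housekeeping genes, 11 were marked (8 and 11), with a median of 32.9% at the 99.99th percentile, led by the chaperone Hsp90ab1 with 70.8% and the elongation factor Eef2 with 60.6%. Of 81 ribosomal protein genes, 49 were marked (30 in replicate 1 and 46 in replicate 2), with a median of 32.6% (17.5% and 27.3%) at the 100th percentile, and Rps5 had 67.2% and Rps3 61.1%.

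The genes that write, erase and read H3K36 methylation were themselves marked in 11 of 16 cases, with a median of 28.4% at the 100th percentile. The demethylase gene Kdm4a had 77.5% of its span covered (57.8% ± 6.68), the methyltransferase gene Nsd1 43.1%, the reader gene Morf4l1 36.1%, and Setd2, which encodes the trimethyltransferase (chromosome 9, 110532597 to 110618633), 32.4% (25.6% ± 8.13). The DNA methyltransferase genes Dnmt3a and Dnmt3b had 27.4% and 4.57%, and Phf19 had none. Setd2 reached 31.4% in replicate 2 and 19.9% in replicate 1. In replicate 1 alone only 2 of the 16 genes were marked, against 10 in replicate 2, although the median stood at the 100th percentile in both.

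Of the 18 genes of cystic kidney and ciliary disease, 6 were marked (5 in each replicate) and all 18 had some coverage, with a median of 12.1% at the 98.43rd percentile (97.85th and 99th in the replicates). The marked genes were Ganab with 60.3%, the tuberous sclerosis genes Tsc2 and Tsc1 with 58.7% and 46.9%, the polycystin genes Pkd2 and Pkd1 with 44.6% and 41.0%, and the von Hippel-Lindau gene Vhl with 26.9%. With the pooled list the percentile was 97.4, and without genes within 5 kb of a marked neighbour it was 94.72 over 11 genes, both short of the threshold. Of 15 measured imprinted genes, Igf2r (31.3%) and Impact (25.6%) were marked (none in replicate 1 and 2 genes in replicate 2), and the list stood at the 53.01st percentile. Igf2, Dlk1 and Cdkn1c had no coverage.

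Few markers of kidney cell types were marked, although the amount of the mark below the caller's limit was not measured. The tissue was not separated into cell types. A mark held by a small share of the cells therefore cannot be told apart from no mark. Of 147 such genes in 8 lists, 5 were marked (3 in replicate 1, 5 in replicate 2 and 10 by the pooled list). Some coverage was found in 32.7% of the 147 by the replicated list and in 61.2% by the pooled list. The 5 were Ccnd1, the cyclin D1 gene (chromosome 7, 144929931 to 144939925), with 44.4% (35.98% ± 12.3), and Jag1, a Notch ligand, with 37.7% (32.6% ± 11.97), both of the early nephron list, and Vegfa (46.6%, 40.7% ± 1.48), the actin crosslinker Actn4 (32.1%, 28.7% ± 3.06) and Foxc2 (28.9%, 22.1% ± 5.99), all of the podocyte list. The medians of the 8 lists stood between the 16.97th and the 77.85th percentile, and none passed the threshold. In 6 of the 8 the median was 0, which leaves the percentile little room to fall. With the mean in place of the median, an alternative chosen after seeing the data, 5 of the 8 lay at or below the 2.5th percentile: ureteric bud and collecting duct (0.04), proximal tubule (0.01), loop of Henle and distal tubule (0.03), endothelium (0.32) and nephron progenitor (1.7, and 3.77 in replicate 2 alone). The means of the remaining lists stood at the 57.6th (podocyte), 34.93rd (early nephron) and 4.77th percentile (stroma and mesangium).

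In the nephron progenitor list 0 of 16 genes were marked, and 1 (Pax2) by the pooled list. Sall1 had 13.8% (7.87% ± 4.02), Pax2 12.9% (13.1% ± 6.71, and 27.9% by the pooled list), and Wt1 4.78% (3.795% ± 2.58). Six2, the transcription factor that maintains nephron progenitors (chromosome 17, 85684277 to 85688274), had no peak in any of the 4 lists, and Dpf3, the longest of the genes with no replicated coverage in this list, had 0.327% ± 0.0248 in the replicates. Besides Ccnd1 and Jag1, the early nephron list held Pax8 with 12.3% and Hnf1b with 12.04%, both marked by the pooled list, while Greb1 had no replicated peak. In the ureteric bud and collecting duct list 0 of 20 genes were marked. Etv5, a target of RET signalling, had 9.72% (8.50% ± 4.82) and Tfcp2l1 5.60% (5.81% ± 1.76), and Ret and Wnt7b had none.

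Of 18 podocyte genes, 9 had no coverage, among them Nphs1, which encodes the slit diaphragm protein nephrin (chromosome 7, 30458315 to 30487223), and Magi2, which spans 1477757 bp. None of the 22 proximal tubule genes was marked. Slc5a2, the gene of a glucose transporter, had 17.5% (15.5% ± 1.02), of which the part outside the marked neighbour BC017158 had 2.36%. Dab2 had 4.50% (4.30% ± 1.81), Slc34a1, the phosphate transporter gene, had no peak in any list, and Cubn had none in the replicated list. Of 20 genes of the loop of Henle and distal tubule, 17 had no coverage, including Umod and Trpm6, and the kinase genes Wnk1 and Wnk4 had 14.2% (13.9% ± 3.22) and 5.64% (5.60% ± 1.66). The stroma and mesangium list had 10 of 19 genes with some coverage and none marked by the replicated list, but 2 by the pooled list. Vim led with 23.5% (17.9% ± 7.75, and 31.8% by the pooled list), then Col1a1 with 14.9% (10.3% ± 1.56, and 29.1% by the pooled list), and Foxd1 and Ntn1 had none. Of 18 endothelial genes 0 were marked. Eng had 13.3% (11.3% ± 2.06), Egfl7 11.6%, all of it within another overlapping gene, and Pecam1 and Erg none.

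Genes of the 6 lists labelled as other tissues were covered less often still. These lists include immune and erythroid cells, which kidney tissue can also hold, so they do not all stand for absent tissues. Of 83 such genes in 6 lists, 6 (7.23%) had any replicated coverage, against 48 of the 147 kidney genes (32.7%), a difference with a two-sided Fisher's exact p of 7.77e-06 over genes. The same exact test gave 14.5% against 55.8% in replicate 2 (p = 3.66e-10) and 9.64% against 52.4% in replicate 1 (p = 1.82e-11). It was chosen after the lists had been measured and did not match genes on length, on which coverage depends. The p-values describe these lists and do not measure a difference between tissues. None of the 15 neuronal and glial genes, among them Snap25 and the 1059441 bp Nrxn1, and none of the 15 hepatocyte genes, among them Alb and Cps1, had a replicated peak. In the erythroid list Epb42 had 1.46% and the other 10 measured genes, including Ank1, none. Hba-a1, the alpha globin gene, falls under the 1 kb minimum and had no peak in any list. Of the muscle genes only Atp2a1 was covered (9.44%, with 0 outside overlapping genes), and Ckm and Neb were not. Of the adrenal genes only Star was covered (8.93%, and over 25% by the pooled list, 13 bp from the marked gene Ash2l), and Mc2r was not. In the immune list Cd68 had 91.1% of its 1941 bp covered (66.1% ± 13.8) and lay 782 bp from the marked translation factor gene Eif4a1. Adgre1 had no peak, Cx3cr1 15.3% and Csf1r 8.07%. With the mean in place of the median, 5 of these 6 lists, all but the immune list, lay at or below the 2.5th percentile, 4 of them in replicate 2 alone.

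**Figure D3:**
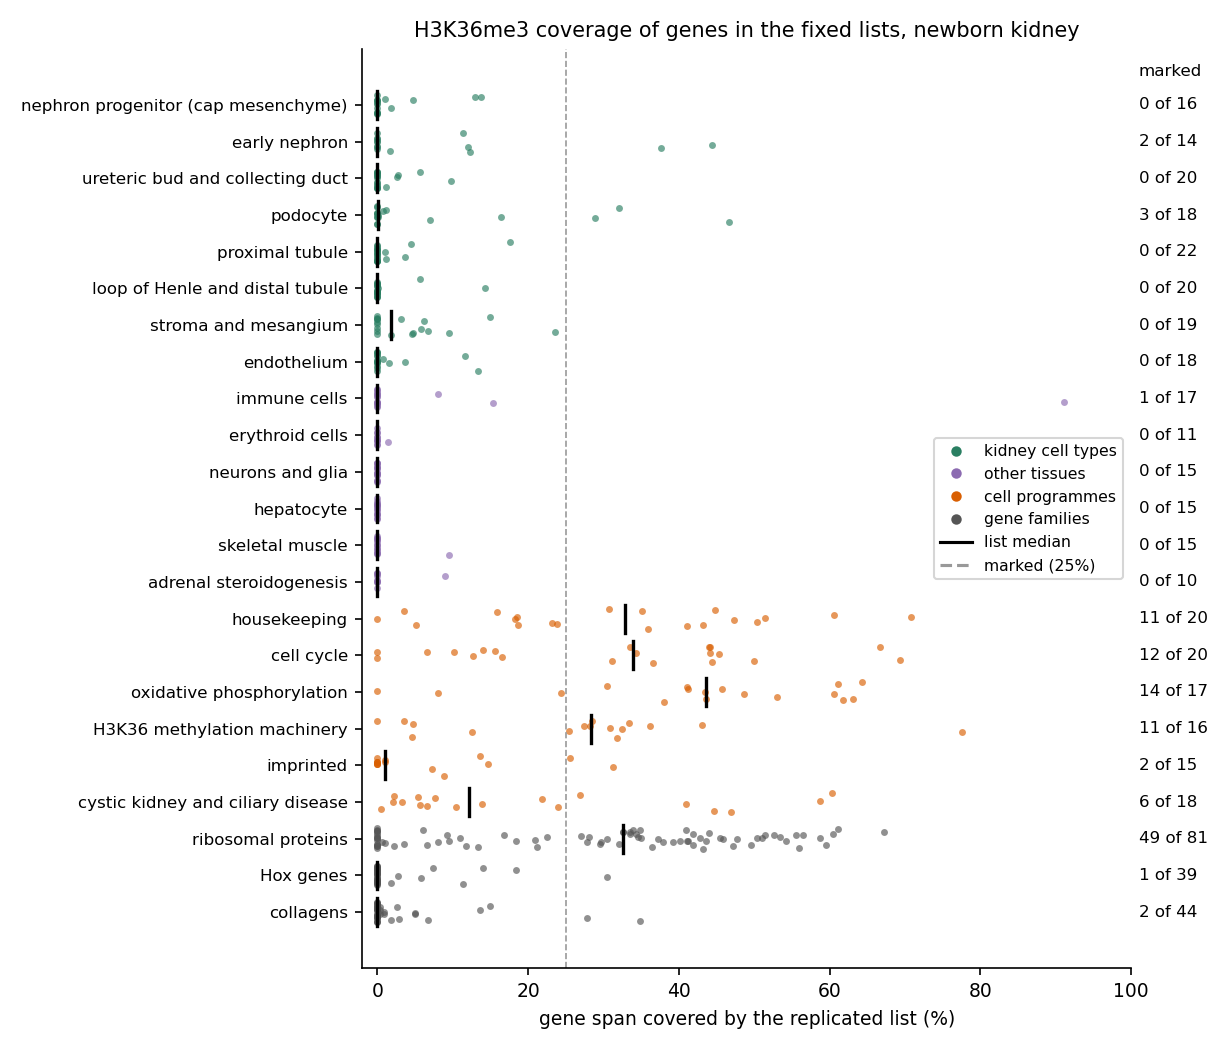
Percentage of each gene's span covered by the replicated H3K36me3 list (horizontal axis) for the members of the fixed lists, with 1 point per gene, a black bar at the list median and a dashed line at the 25% that calls a gene marked. The counts on the right give marked over measured genes, from 14 of 17 for oxidative phosphorylation to 0 of 15 for hepatocyte and for neuronal genes.

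Gene families ran from no replicated coverage to the level of the cell programmes. Members shorter than the 1 kb minimum were not measured, so families of short genes are not complete. None of the measured 1029 olfactory receptor genes, 273 vomeronasal receptor genes, 19 replication-dependent histone genes or 17 keratin-associated protein genes had any replicated coverage. The percentiles of their means were 0, 0, 1.15 and 5.955. Zfp genes, which encode zinc finger proteins, were marked in 111 of 394 cases (65 in replicate 1 and 95 in replicate 2), with a median of 10.4% (replicates 9.97% ± 2.64) at the 100th percentile. Of 39 Hox genes, Hoxb4 (30.4%, 19.5% ± 4.32) was the only one marked, in neither replicate's own list, and 31 had no coverage. Of 44 collagen genes, Col4a1 (34.9%, with 24.1% in replicate 1 and 35.4% in replicate 2) and Col4a2 (27.8%, with 19.4% and 26.4%), which encode basement membrane collagen, were marked, though neither in replicate 1. Solute carriers were marked in 34 of 348 cases (16 in replicate 1, 25 in replicate 2 and 59 by the pooled list), and their median was at the 7.3rd percentile by the replicated list but at the 0.11th and 0.07th in the replicates. Of 100 cytochrome P450 genes, the sterol demethylase gene Cyp51 (27.1%, with 18.3% in replicate 1 and 27.1% in replicate 2) and Cyp2t4 (25.2%, with 19.4% and 17.7%) were marked, so that replicate 1 alone marked none. None of the 56 clustered protocadherins was marked by the replicated list and 1 was by the pooled list.

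The X chromosome stood apart from the autosomes. Of 877 X-linked genes, 5 were marked (0.570%, exact 95% interval 0.185 to 1.33), against 3518 of 20156 autosomal genes (17.5%) and 15.9% of autosomal genes of matched length. The 5 were Flna, the filamin A gene (X, 74223461 to 74249820), with 45.0% (29.0% ± 6.28), the histone demethylase gene Kdm5c with 39.3% (28.4% ± 0.310), Hcfc1 with 28.2%, Ddx3x with 28.2% and Cdk16 with 25.5%. In replicate 1, 0.114% of X-linked genes and 10.7% of autosomal genes were marked, and in replicate 2 the shares were 0.342% and 15.6%. By the pooled list 16 X-linked genes were marked (1.82%), against 24.6% of autosomal genes. The replicated list had 2.53 peaks per Mb on the X and 39.1 per Mb on the autosomes, 15.5 times as many. The other lists gave smaller ratios, of 10.9 in replicate 1, 11.2 in replicate 2 and 6.85 in the pooled list. Among the autosomes the share of marked genes ran from 12.6% on chromosome 14 to 22.4% on chromosome 8, and 0 of 163 genes on the Y chromosome were marked (exact 95% interval up to 2.24%). The intervals cover counting of genes only. Since sexes were pooled, the X and Y values describe a mixture of male and female tissue. Mappability on the Y was not measured, so the absence of marked Y genes is an absence of called peaks.

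**Figure D4:**
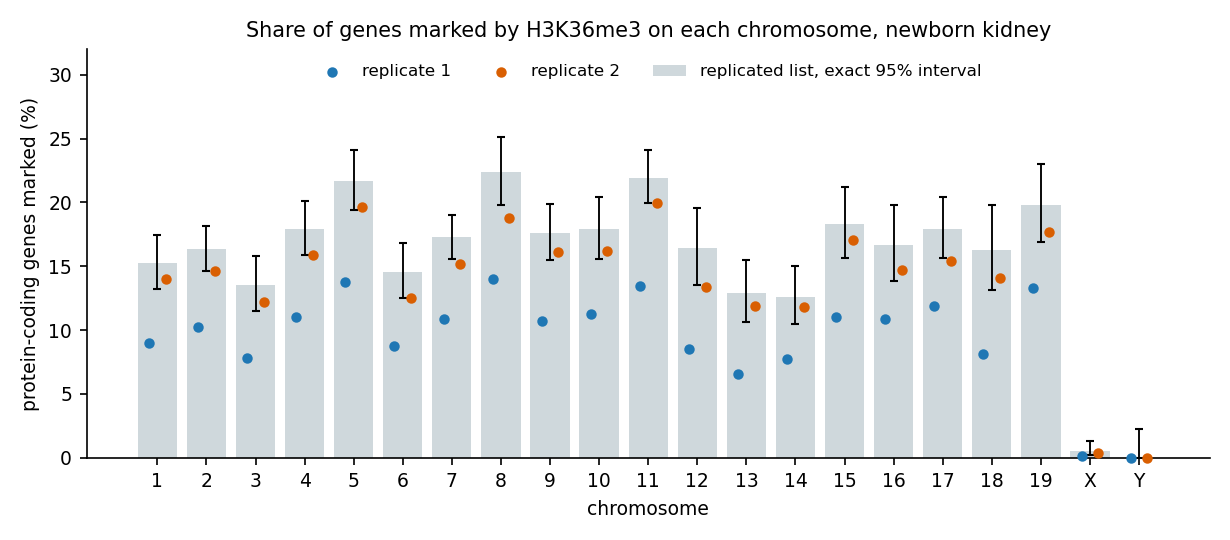
Percentage of protein-coding genes of at least 1 kb marked by H3K36me3 (vertical axis) on each chromosome (horizontal axis), with bars for the replicated list, error bars for the exact 95% binomial interval over genes, and points for each replicate's own list. Autosomes ran from 12.6% to 22.4%, the X stood at 0.570% and the Y at 0.

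Marked regions away from annotated genes were not found on chromosomes 1 to 19, X and Y; unplaced scaffolds were left out. Replicated peaks merged across gaps of up to 3 kb gave 6509 regions of at least 5 kb, and 0 of these lay at least 5 kb from every annotated gene. With the pooled list 2 such regions were found, with replicate 2 alone 4, and with distances taken from protein-coding genes only 11.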

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

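Replicated peaks in 2 places lay outside the chromosomes and genes measured above. They are given because each number passed a fixed limit of 3 used to screen data left out of the comparisons, which does not say how many peaks these sequences should hold. On unplaced scaffolds of the assembly 8 replicated peaks were found, 7 of them within the scaffold 4_GL456216_random between 30529 and 36135. The strongest of these, from 34046 to 35068, had a deposited signal value of 8.15 and a −log10 p of 29.0, which places it among the 10 strongest peaks of the replicated list. On the Y chromosome 6 replicated peaks were found, all between 90737479 and 90742231, the strongest with a −log10 p of 16.1, and none of the 163 Y-linked protein-coding genes had any coverage. No explanation was tested for either.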

How the results depend on the processing

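Alternatives that leave out a replicate use the other replicate's own list, and the alternatives by mean, by neighbours and by matching on GC content and repeats were chosen after the data were seen. The 7 lists called above random lists kept that call under every alternative run for lists, except the cystic kidney list with the pooled list (97.4) and without genes within 5 kb of a marked gene (94.72, over 11 of its 18 genes). The removal of the 1% of peaks with the highest signal value left 60.6 Mb covered. Lists were not rerun with gaps merged or without overlapping genes. No paired analysis was possible because there was 1 group. Read depth was not given in the sources used here, so the lowest level of the mark that could have been called is unknown.

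The share of replicate 1 peaks found in replicate 2 was 67.5% with an overlap of 1 bp, 50.5% with both lists at −log10 p of at least 5, 47.0% with equal numbers of top peaks and 30.4% with 50% of both peaks. The share of replicate 2 peaks in replicate 1 was 52.9%, 29.7%, 40.7% and 24.1% in that order. The Jaccard index was 26.4% at −log10 p of at least 5. With 1 bp, 78.3% of replicated peaks were covered in both replicates.

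With the pooled list, the fold over the genome was 5.25 for exons, 1.72 for introns, 0.0922 upstream, 0.583 downstream and 0.00523 elsewhere, 96.3% of covered bp lay in genes, and the 3' to 5' ratio was 1.89 over the genes that list marks. With the upper 50% of peaks by signal value these were 6.36, 1.61, 0.0611, 0.437, 0.000987, 97.4% and 2.13. Over single replicates they ran from 5.56 to 5.79, 1.66 to 1.68, 0.0869 to 0.0890, 0.511 to 0.559, 0.00524 to 0.00596, 96.4% to 96.7% and 1.87 to 1.90. In all genes of at least 10 kb with any coverage the ratio was 2.28.

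Marked genes numbered 4983 with the pooled list, 4450 with gaps of up to 1 kb merged, 2157 to 3140 over single replicates, 2171 with the upper 50% of peaks, 6221 at a level of 10% and 934 at 50%. The X minus the length-matched autosomal share was -20.7 points with the pooled list, -9.71 with the upper 50% of peaks, -25.7 at 10%, -4.23 at 50% and from -13.8 to -9.64 over single replicates. Regions outside genes numbered 2 with the pooled list, 0 to 4 over single replicates and 11 away from protein-coding genes only.

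With the mean in place of the median, 18 lists moved past the lower threshold, with percentiles of 1.7 (nephron progenitor), 0.04 (ureteric bud), 0.01 (proximal tubule), 0.03 (loop of Henle), 0.32 (endothelium), 0.08 (erythroid), 0 (neurons), 0.02 (hepatocyte), 0.2 (muscle), 1.2 (adrenal), 0 (olfactory), 0 (vomeronasal), 1.15 (histones), 0.66 (Hox), 0.21 (protocadherins), 0 (solute carriers), 0 (P450) and 0.16 (collagens). In replicate 2 alone 15 lists did, since nephron progenitor (3.77), adrenal (2.7) and Hox (4.88) fell short. Where more than 50% of a list has no coverage its median is 0, which ties with many random lists; a mean of 0 ties only with lists in which no gene is covered. Solute carriers stood at 0.05 with the pooled list and from 0.07 to 0.11 over single replicates, and P450 genes at 1.645 with the pooled list. With genes of at least 5 kb only, the clustered protocadherins moved from 41.68 to 99.575, over 39 of 56 genes; their annotated spans overlap one another, and the cause was not tested further.

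Over all results recomputed, including the coverage of the genes named by rule, a value was counted as moved where it changed by more than the SD between replicates, or for a count by more than 1.5 times, and a list as unchanged where its call stayed. With the pooled list 36 moved and 64 stayed, and the rest were lists whose call changed. On the same terms results moved in 33 and stayed in 69 without replicate 1, moved in 35 and stayed in 67 without replicate 2, moved in 32 and stayed in 71 with the upper 50% of peaks by signal value, and moved in 24 and stayed in 39 with peaks merged across gaps of up to 1 kb.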

Other observations

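The tests of gene content on the X, the comparison of zinc finger genes and the values on the strongest peaks were chosen after the data had been seen; the matched comparisons of the X and of exons were set out before their results.

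Zinc finger genes held many of the strongest peaks. Of the 10 replicated peaks with the highest deposited −log10 p, 5 overlapped Zfp genes (Zfp865, Zfp110, Zfp157, Zfp180 and Zfp27), and in each of these the peak covered the last exon over at least 50.5% of its length. In Zfp865 (chromosome 7, 5029241 to 5034071) the whole peak of 4831 bp lay in exons. The exonic share of the peak was 33.3% in Zfp110, 47.4% in Zfp180, 87.2% in Zfp27 and 88.2% in Zfp157. Among the 1% of replicated genic peaks with the highest signal value, 59 of 908 lay in Zfp genes (6.50%, exact 95% interval 4.98 to 8.30), against 1.96% of all genic peaks, a ratio of 3.31 (2.06 in replicate 1 and 2.67 in replicate 2). The interval counts peaks as independent, although peaks of the same gene are not. The median signal value of Zfp peaks was above that of other genic peaks in the replicated list (3.89 against 3.76) and replicate 1 (3.63 against 3.48). It was equal to theirs in replicate 2 (3.55) and the pooled list (3.17). In 85 marked Zfp genes of at least 10 kb with at least 3 exons, the last exon was covered at 59.7% (48.8% ± 5.87, SD, n = 2) and internal exons at 56.6% (44.3% ± 6.85). In the 2516 other genes the order was the opposite, with 52.8% (41.1% ± 5.30) and 61.4% (48.7% ± 6.55). The last exon had a median length of 2885 bp in the Zfp genes and 1319.5 bp in the others. The peak with the highest −log10 p (38.01) spanned 8119 bp on chromosome 1 (88262259 to 88270377) across the 3' part of Hjurp, which encodes the chaperone of the centromeric histone CENP-A, and held the whole of its last exon. Shroom3, a gene linked to epithelial cell shape, had a peak of 3332 bp with a −log10 p of 30.5, of which 96.0% was exonic, while 4.66% of the gene's whole span was covered.

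Long noncoding genes away from protein-coding genes were rarely marked. Of 4267 such lincRNA genes, 2 reached 25%: Mir17hg, the host gene of the miR-17 to miR-92 cluster (chromosome 14, 115042879 to 115046727), with 61.1% (22.8% in replicate 1 and 50.7% in replicate 2), and Malat1 (chromosome 19, 5795690 to 5802672) with 40.9% (29.3% and 44.1%). Snhg20 followed with 23.4%. Of 1582 processed pseudogenes under the same condition, 2 were marked.

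Few X-linked genes were marked (0.570%, against 17.5% of autosomal genes). The kinds of genes on the X are argued against as the whole cause, on the basis of 6 genes only. These X-linked members of 4 broadly expressed lists (Hprt, Pgk1, Rpl10, Rpl36a, Rpl39 and Rps4x) had a mean coverage of 4.47% against 32.01% for 130 autosomal members, a ratio of 0.140 (two-sided permutation p over genes 0.00092, with ratios of 0.118 and 0.107 in the replicates). They belong to the housekeeping and ribosomal protein lists, while the autosomal members also come from the cell cycle and oxidative phosphorylation lists. The X-linked ribosomal protein genes had no coverage in the replicated list or in either replicate, while Pgk1 had 23.2% in the replicated list. Gene length, GC content and repeats are argued against too, since autosomal genes matched on all 3 were marked in 13.1% of cases, 22.9 times the X share (63.0 and 34.6 times in the replicates). The dose of the X, with a single active copy per cell and pooled sexes, and the way the caller set its control on the X stay open, because control reads and read depth were not used here. The design names no biological contrast for this pattern, so no biological explanation was tested.

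In marked genes, exons were covered more often than introns: 500 bp windows with at least 100 exonic bp were covered at 56.3% and windows with none at 31.3%, a ratio of 1.80 (1.86 and 1.73 in the replicates). GC content and repeats are argued against as the whole cause, since intronic windows matched on both left a ratio of 1.71 (1.72 and 1.67 in the replicates). Position along the gene is argued against as the whole cause, since windows matched on which of 10 equal parts of the gene they lay in left 1.52 (1.59 and 1.49), and matching on all of these left 1.43. The fall from 1.80 to 1.43 shows that these properties go with part of the difference. Windows were pooled over the marked genes and were not matched on the gene they came from. Differences between genes, such as length, can therefore be part of these ratios and stay open. Nucleosome density and mappability were not measured and stay open, and no biological explanation was tested.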
